A study of Mus musculus with 12 samples.

How the data were processed

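RNA of hepatocytes from male floxed and hepatic Rxra-knockout mice, each with and without bexarotene, was sequenced as 12 libraries, 3 per group. Per the labels, RNA was extracted with TRIzol, treated with DNase I and made into libraries with an Illumina stranded mRNA kit from 1 µg of total RNA. Per the submitters' processing notes, reads were trimmed with fastp, aligned with HISAT2 and quantified with StringTie, with no versions stated; whether counting was stranded is not stated, and the genome build is not given in the sources used here. The authors deposited 1 table of TPM (read coverage scaled for transcript length and for the library total) for 26748 Ensembl gene identifiers, of which 21810 could be given a symbol. Counts were not given, so the depth of each library is unknown, and the precision of low values cannot be stated from depth. The columns number the libraries of a group differently from the sample titles, so columns were assigned to groups only, and libraries are named here by their column numbers: floxed control 1, 3 and 4, floxed bexarotene 1, 3 and 4, knockout control 1, 2 and 5, and treated knockout 1, 2 and 3. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

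Each pair of libraries within a group was compared over genes of at least 10 TPM in 20 classes of expression. The part of their log2 difference that does not shrink with TPM times transcript length was taken as the spread beyond counting noise. Transcript length and GC content came from GENCODE M21 and covered 95.2% of the tested genes. Libraries of a group with a spread under 0.1 log2 were averaged into 1 sample. This limit was chosen after the values were seen, and it left 9 samples in place of the 12 planned before the data were examined. The planned fit to 12 libraries was run as an alternative.

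Genes with at least 1 TPM in at least 3 libraries were tested, 11018 in all, 10490 of them with a symbol. Linear models were fitted to log2(TPM + 1) over all 4 groups with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend; 5 residual degrees of freedom, prior degrees of freedom 3.22). The contrasts were bexarotene against control in each genotype, knockout against floxed without and with bexarotene, and the difference between the 2 bexarotene effects. Fold changes are differences on the log2(TPM + 1) scale, which understates changes of genes near 0 TPM. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene is said to be called, or to have risen, fallen or changed, at an adjusted p under 0.05. The lone treated knockout sample is assumed to vary like the other groups.

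Of 37 gene lists written from general knowledge before the data were examined, 34 had at least 3 tested members and were tested with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated for each list. P-values of lists were adjusted over the 34 lists of a comparison. Some lists share members, so their calls are not separate evidence. Scd1 is on the lipogenesis and LXR lists and Thrsp on the lipogenesis and thyroid lists. Gsta1 is on the CAR and PXR list and the NRF2 list. Members were also adjusted over their list alone. Lists for stellate cells, pancreatic acinar cells and adipocytes or muscle had too few tested members. The lists of other cell types serve as markers.

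Genes were named by a rule fixed before the data were examined, which took the 3 RXR genes first. It took up to 8 called genes each with the largest rise and fall, except in knockout against floxed under bexarotene. These had at least 5 TPM in the highest group compared and, except for the difference between genotypes, groups whose samples did not overlap. In each list it took up to 4 called members with the smallest adjusted p, or otherwise the 2 with the highest TPM. A gene named for one comparison may be given in the others. Not all of these are printed, some genes are not reported here, and the few genes named outside the rule are given as chosen later. Genes with no name or a predicted one are only counted. Values of near-identical genes, such as the Mup, Cyp2c, Cyp4a, Acot, Gsta and Saa families, are uncertain because reads can be split among the copies.

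The tests were tested on simulated data: 200 genes with a mean log2(TPM + 1) above that of 5 TPM were changed on the spread of these samples. The median tested gene stood at 5.61 to 6.7 TPM per library. The shares recovered therefore say nothing about the many tested genes of lower level. A log2 change of 1 was recovered for 72% of genes in bexarotene against control in floxed mice, 34% in knockout mice, 70% in knockout against floxed without bexarotene, 35% under bexarotene and 8% in the difference between genotypes. A log2 change of 2 was recovered for 96%, 93%, 98%, 92% and 80%, and between 5 and 16 of 93 to 184 calls were false. In each of the 5 comparisons a list shifted by 0.5 was called, and 0 other lists were. The genes were simulated without correlation, and every sample, the single treated knockout included, was given the same spread per gene. Knockout controls in fact differed by 0.250 to 0.503 beyond counting noise, and floxed libraries that were not averaged by 0.151 to 0.231. The shares recovered may therefore be too high for comparisons with knockout controls and too low for bexarotene in floxed mice.

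The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, rescaling by the median ratio, quantile normalization, leaving out the 20 most abundant and the mitochondrial genes, a robust empirical Bayes step, array weights, a minimum log2 change of 1, fitting only the groups compared, an estimated correlation for lists, and leaving out each library. Added after the data were seen were averaging the next closest pair, leaving out both averaged floxed controls, removing the trend with GC content and length, and a block of column numbers. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads, splicing, the deleted exons and genes without expression in 3 libraries were not analysed here.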

Results

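Hepatocytes from male C57BL/6 mice were profiled by RNA sequencing to compare the response to bexarotene in the presence and absence of RXRα. Bexarotene is a drug that binds and activates retinoid X receptors (RXRs). RXRα, the product of Rxra, is a nuclear receptor that binds DNA in pairs with other receptors, among them PPARα, LXR, FXR, CAR, PXR and the receptors for thyroid hormone and retinoic acid. The 12 libraries fell into 4 groups of 3: floxed mice, in which the gene is intact, without and with bexarotene at 100 mg/kg per day for 5 days, and mice with a hepatic knockout of Rxra without and with the same treatment. The deposited table gave TPM for 26748 gene identifiers, and between 9713 and 10470 genes per library reached 1 TPM. The 20 genes with the highest TPM took 36.3% to 42.2% of each library. TPM keeps no read totals, so the depth of the libraries is unknown.

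Some libraries of one group were close to identical. Of the 12 pairs of libraries within a group, 4 differed beyond counting noise by an SD of only 0.0384 to 0.0666 on the log2 scale, which is 2.70% to 4.72%, while the other 8 pairs differed by 0.151 to 0.503. The close pairs were floxed controls 1 and 3 and every pair among treated knockout libraries 1, 2 and 3. They differed by little more than sampling noise, so each set was averaged and counted as 1 sample. This left 9 samples: n = 2 floxed controls, n = 3 treated floxed samples, n = 3 knockout controls and n = 1 for the treated knockout. Means ± SD below are over these samples, and the treated knockout has no SD. The fit to 12 separate samples, planned before the data were examined, called 1062 genes for bexarotene in floxed mice and 1105 in the knockout, 1302 and 1589 for the knockout without and with the drug, and 651 for the difference.

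**Figure D1:**
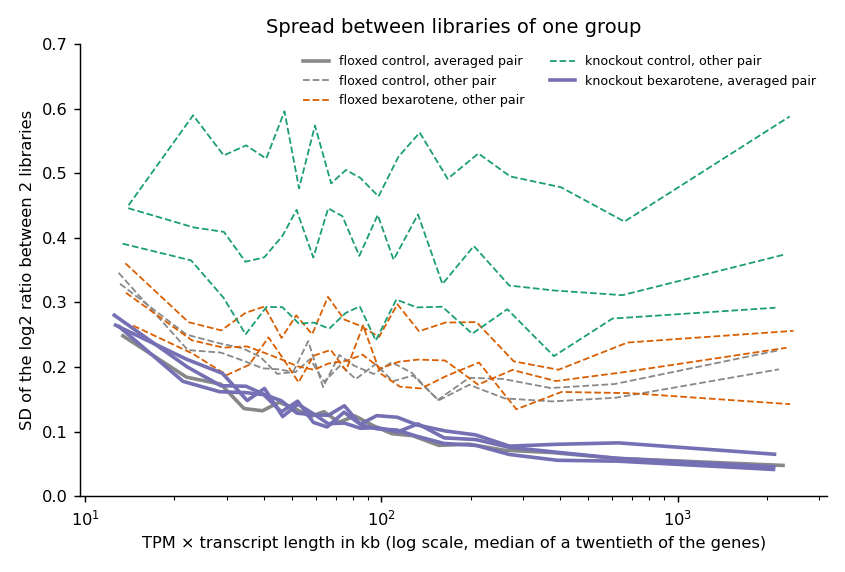
Each line is a pair of libraries from one group; the y axis is the SD of their log2 ratio and the x axis (log scale) is TPM times transcript length in kb, as medians over twentieths of the genes. The 4 solid lines are the averaged pairs, which fall to 0.0413 to 0.0649 for the most abundant genes, and the 8 dashed lines are the other pairs, which stay between 0.142 and 0.588 there.

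Rxra itself was lower in the libraries labelled as knockout. It stood at 82.9 ± 4.47 TPM (SD, n = 2) in floxed controls, 82.4 ± 2.87 (n = 3) in treated floxed samples, 30.4 ± 3.18 (n = 3) in knockout controls and 26.8 in the treated knockout. No knockout library exceeded 33.1 TPM and no floxed library was below 79.5 TPM. Rxra fell by 1.42 ± 0.13 on the log2 scale (± SE, adjusted p = 8.87e-04, limma with Benjamini-Hochberg adjustment) in controls and by 1.58 ± 0.16 under bexarotene (adjusted p = 0.00247). These gene-level values cover all exons, so transcripts that lost the deleted part cannot be told from intact ones. Rxrb stood at 10.7 ± 1.05, 12.9 ± 0.268, 10.6 ± 2.93 and 13.1 TPM in the same order and Rxrg at 1.51 ± 0.449, 1.37 ± 0.180, 1.05 ± 0.165 and 0.99 TPM. Neither passed the test in any comparison. The 3 RXR genes as a list were lower in knockout controls (median -0.29, adjusted p = 0.0265, adjusted p = 0.267 with an estimated correlation), a call that was lost without knockout control 2 or 5 (adjusted p up to 0.0681). The list holds the deleted gene Rxra, so this call says little about Rxrb and Rxrg. Bexarotene left Rxra at a log2 fold change of -0.0082 ± 0.13 in floxed mice (adjusted p = 0.986).

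**Figure D2:**
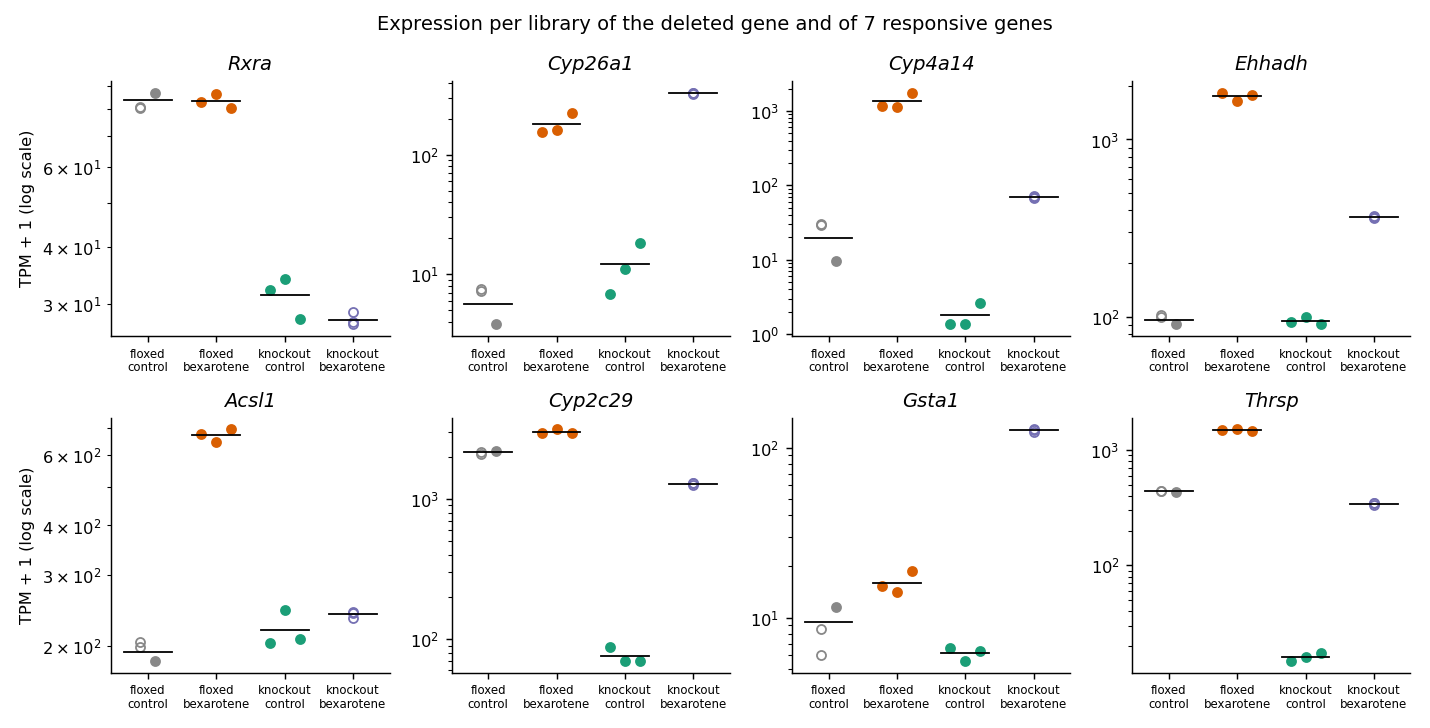
TPM + 1 (y axis, log scale) per library for Rxra and 7 responsive genes in the 4 groups; open circles are libraries averaged into 1 sample, filled circles are single samples and lines are group means. Rxra separates the genotypes (82.9 and 82.4 TPM against 30.4 and 26.8), while Ehhadh rises to 1754 TPM in treated floxed mice and 365 in the treated knockout.

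In floxed mice targets of PPARα and of CAR and PXR were higher with bexarotene as lists. Clock genes, described below, also set the treated floxed samples apart from their controls. Any difference in sampling time between these groups therefore cannot be separated from the drug in the changes that follow. Lipogenesis genes rose too, by a list call that was lost with an estimated correlation (adjusted p = 0.263). Cyp4a14, a fatty acid omega-hydroxylase, went from 18.7 ± 14.1 to 1344 ± 363 TPM (log2 fold change 6.27 ± 0.48, adjusted p = 5.68e-04). Cyp26a1, which degrades retinoic acid, went from 4.60 ± 2.55 to 179 ± 39.2 TPM (5.06 ± 0.42, adjusted p = 8.31e-04). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, went from 94.7 ± 7.19 to 1754 ± 94.3 TPM (4.20 ± 0.11, adjusted p = 2.10e-06). In all, 234 of 11018 tested genes changed, 203 higher and 31 lower, of which 21 have no name or only a predicted one. With the GC and length trend removed 225 were higher and 89 lower (71.7% higher in place of 86.8%), and with quantile normalization 76.8% were higher.

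Targets of PPARα, the receptor that switches on fat burning in the fasting liver, rose as a group. Of 43 tested members 21 rose, 31 when adjusted over the list alone. The list passed the camera test, which gives all list values below (median log2 fold change 0.93, adjusted p = 3.96e-29, and adjusted p = 0.0396 with an estimated correlation). Besides Ehhadh these included the acyl-CoA thioesterase Acot2 (3.65 ± 0.19), the carnitine transporter Slc22a5 (2.36 ± 0.16) and the acyl-CoA synthetase Acsl1, which went from 192 ± 13.1 to 673 ± 25.1 TPM (1.81 ± 0.12). Acot3 (4.22 ± 0.30) and Acot1 (3.54 ± 0.55), close paralogs of Acot2, rose too, and their shared sequence leaves the split of reads among them uncertain. Targets of CAR and PXR, receptors that respond to drugs and other foreign chemicals, also rose. Of 36 members 8 rose, and 14 rose and 1 fell when adjusted over the list alone (median 0.40, adjusted p = 1.09e-05, adjusted p = 0.0396 with an estimated correlation). Among them were Akr1b7 (3.79 ± 0.17), the glutathione transferases Gsta2 (2.33 ± 0.12) and Gstt3 (2.03 ± 0.19), and Por, the electron donor of microsomal cytochromes P450, which went from 165 ± 42.6 to 824 ± 54.6 TPM (2.34 ± 0.24).

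Lipogenesis genes and LXR targets rose as lists, by calls that were lost with an estimated correlation. Of 22 lipogenesis genes 6 rose, 10 rose and 1 fell when adjusted over the list alone (median 0.62, adjusted p = 3.57e-05, adjusted p = 0.263 with an estimated correlation). Thrsp, a regulator of lipogenesis that responds to thyroid hormone, went from 437 ± 5.52 to 1487 ± 22.7 TPM (1.76 ± 0.11). Srebf1 (1.85 ± 0.31) and Mlxipl (1.45 ± 0.22), which encode the lipogenic transcription factors SREBP1 and ChREBP, and Acaca (1.44 ± 0.22), the acetyl-CoA carboxylase, rose as well. Of 12 LXR targets 4 rose and 1 fell, 5 and 1 over the list alone (median 0.51, adjusted p = 0.00172, adjusted p = 0.298 with an estimated correlation). The sterol exporters Abcg8 (1.62 ± 0.14) and Abcg5 (1.66 ± 0.18) rose and lipoprotein lipase, Lpl, fell (-1.18 ± 0.19). The lipid droplet gene Cidec rose (2.49 ± 0.20), and its list did not pass (median 0.27, adjusted p = 0.0618). Among 10 genes induced by the bile acid receptor FXR, 3 rose, 6 over the list alone (median 0.62, adjusted p = 7.01e-04, adjusted p = 0.263 with an estimated correlation). They included Slc51b, part of the basolateral bile acid exporter (1.75 ± 0.16), and the bile salt export pump Abcb11 (1.19 ± 0.22). Cyp8b1, which sets the share of cholic acid, fell from 285 ± 19.1 to 47.1 ± 20.8 TPM (-2.65 ± 0.30), and so did Csad, an enzyme of taurine synthesis (-2.33 ± 0.22). The other largest falls were of Camk1d (-2.27 ± 0.41), Gas6 (-1.68 ± 0.23), the immunoglobulin gene Ighv1-9 (-1.61 ± 0.21), Dnajc12 (-1.49 ± 0.29), Enho (-1.41 ± 0.28) and Dpy19l1 (-1.13 ± 0.20). The bile acid list as a whole did not pass (median 0.081, adjusted p = 0.962), nor did cholesterol synthesis and uptake (median 0.079, adjusted p = 0.819).

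Ccnd1, the cyclin that drives cells out of G1, went from 1.84 ± 0.587 to 42.5 ± 1.20 TPM (3.95 ± 0.18, adjusted p = 4.67e-05). It was the 1 called gene among 25 cell cycle genes, of which 8 rose when adjusted over the list alone (median 0.61, adjusted p = 1.28e-06, adjusted p = 0.263 with an estimated correlation). Amino acid catabolism and urea cycle genes rose on balance, with 4 of 35 members up and 1 down, 14 and 3 over the list alone (median 0.37, adjusted p = 0.00172, adjusted p = 0.263 with an estimated correlation). Aass, which starts lysine breakdown, rose (2.31 ± 0.16) and the aspartate aminotransferase Got1 fell (-1.12 ± 0.19). Glucose metabolism had 0 of 18 called and 7 higher over the list alone (median 0.52, adjusted p = 0.00198, adjusted p = 0.300 with an estimated correlation). Of 15 periportal genes 1 rose, 5 over the list alone (median 0.38, adjusted p = 0.00573, adjusted p = 0.298 with an estimated correlation). Of 16 pericentral genes 1 rose, and over the list alone 1 rose and 1 fell (median -0.28, adjusted p = 0.00565, adjusted p = 0.263 with an estimated correlation). The called member, the fatty aldehyde dehydrogenase Aldh3a2, rose (1.08 ± 0.15) while its list as a whole fell. Without floxed bexarotene 4, or without floxed controls 1 and 3, the pericentral call was lost (adjusted p up to 0.319).

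Several lists fell with bexarotene in floxed mice. They were acute phase genes (median -0.36, adjusted p = 0.0175, adjusted p = 0.651 with an estimated correlation) and complement and coagulation genes (median -0.11, adjusted p = 0.0158, adjusted p = 0.641 with an estimated correlation). Integrated stress and ER stress genes (median -0.23, adjusted p = 0.00283, adjusted p = 0.173 with an estimated correlation) and male-biased genes (median -0.27, adjusted p = 0.00149, adjusted p = 0.234 with an estimated correlation) fell too. Over these lists the called members were Il1rn (1.97 ± 0.28) and Cyp4a12b (2.03 ± 0.15), both of which rose. Over each list alone, 1 acute phase gene rose and 1 fell, 1 stress gene rose and 1 fell, 1 male-biased gene rose and 3 fell, and 0 complement genes did either. Markers of other cells were also lower. This held for macrophage markers in 12 of 12 genes (median -0.55, adjusted p = 0.00308, adjusted p = 0.593 with an estimated correlation) and endothelial markers in 10 of 12 (median -0.25, adjusted p = 0.00672, adjusted p = 0.572 with an estimated correlation). It held for lymphocyte markers in 5 of 5 (median -0.59, adjusted p = 0.0139, adjusted p = 0.445 with an estimated correlation) and neutrophil markers in 4 of 4 (median -1.17, adjusted p = 4.35e-04, adjusted p = 0.263 with an estimated correlation). Without floxed control 4, the macrophage median was 0.04 and its call was lost (adjusted p = 0.634 in that fit), as were those of the acute phase (0.411), endothelial (0.262), lymphocyte (0.357) and complement lists (up to 0.0667). Floxed bexarotene 4, the treated floxed library with the highest macrophage level (2.59), stayed in that fit. In order of column number the level was 1.64, 1.77 and 2.97 in floxed controls and 1.36, 1.45 and 2.59 in treated floxed libraries. It was thus lower with bexarotene at each shared number. Floxed controls 1 and 3 count as 1 sample here, though, and whether the numbers mark pairs is not known.

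The remaining lists did not pass in floxed mice. Retinoid genes (median -0.028, adjusted p = 0.962) held Cyp26a1 and Retsat (1.30 ± 0.22) as called members, and thyroid hormone responsive genes held Thrsp and Gpd2 (1.32 ± 0.13). The thyroid list had a median of -0.052 and a positive mean (adjusted p = 0.913). Among apolipoprotein and triglyceride clearance genes Apoc2 (1.02 ± 0.14), Lipg (1.49 ± 0.24), Scarb1 (1.01 ± 0.12), Mttp (0.80 ± 0.12) and Lpl were called (median 0.25, adjusted p = 0.145). RXR partner receptors (median -0.016, adjusted p = 0.962) had Nr1i2, which encodes PXR, higher (0.71 ± 0.11). NRF2 targets (median 0.14, adjusted p = 0.398) had Gsta2 up and Gclc down (-1.13 ± 0.19), clock genes (median 0.37, adjusted p = 0.146) had Ciart up (2.25 ± 0.35) and cholangiocyte markers (median 0.034, adjusted p = 0.208) had Krt23 up (3.08 ± 0.23). Among these, Retsat, Apoc2, Lipg, Scarb1, Nr1i2, Gclc and Ciart lost their calls without floxed control 4 or other single samples (adjusted p up to 0.254). The clock list mixes genes that peak at opposite times of day, so its median can hide a shift between them. The mean log2 gap between evening and morning clock genes was -0.869 and -1.54 in floxed controls and 1.76 to 2.53 in treated floxed samples. No member was called by limma among RXR isotypes (adjusted p = 0.962), female-biased genes (median 0.30, adjusted p = 0.962) or immediate early and heat shock genes (median -0.14, adjusted p = 0.244). The same held for hepatocyte identity genes (median -0.0074, adjusted p = 0.127), erythroid genes (median -0.16, adjusted p = 0.913) and mitochondrially encoded genes (median -0.081, adjusted p = 0.913). The mean had the opposite sign to the median for RXR isotypes, RXR partner receptors, retinoid, mitochondrially encoded and bile acid genes.

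The number of called genes for bexarotene in floxed mice rested on few samples: it was 47 without floxed control 4, 69 without floxed controls 1 and 3, 60 without floxed bexarotene 1, 62 without floxed bexarotene 3 and 554 without knockout control 5. Of the genes named for this comparison, the calls of Acot1, Srebf1, Mlxipl, Acaca, Abcg5, Lpl, Abcb11, Cyp8b1, Got1, Aldh3a2, Il1rn and the 6 genes from Camk1d to Dpy19l1 were lost without floxed control 4 or, for most, other samples. The highest adjusted p ran from 0.0535 for Abcg5 to 0.353 for Dnajc12.

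In knockout mice CAR and PXR targets, PPARα targets and lipogenesis genes were higher with bexarotene and acute phase genes lower, by tests that take much of their spread from the other groups. Of these lists CAR and PXR targets kept the call with an estimated correlation, while the others lost it (adjusted p = 0.170, 0.206 and 0.226). Cyp2c29, a cytochrome P450 induced through CAR, went from 75.2 ± 10.3 TPM (n = 3) to 1283 TPM (n = 1; log2 fold change 4.08 ± 0.17, adjusted p = 3.17e-05). The glutathione transferase Gsta1 went from 5.20 ± 0.561 to 125 TPM (4.35 ± 0.28, adjusted p = 5.39e-04). Thrsp went from 15.1 ± 1.35 to 342 TPM (4.41 ± 0.14, adjusted p = 8.65e-06) and Scd1, the desaturase that makes oleic acid, from 329.7 ± 138 to 6785 TPM (4.44 ± 0.44, adjusted p = 0.00499). Cyp26a1 rose here as well, from 11.1 ± 5.83 to 325 TPM (4.88 ± 0.54, adjusted p = 0.00868). In all, 57 genes changed, 46 higher and 11 lower, and quantile normalization gave 69.8% higher in place of 80.7%. The lone treated sample was assumed to vary like the other groups. With only the 2 knockout groups in the fit, 6 genes were called, 6 higher and 0 lower.

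CAR and PXR targets rose in 11 of 36 members, and in 26 when adjusted over the list alone (median 1.33, adjusted p = 3.08e-28, adjusted p = 0.00152 with an estimated correlation). Cyp2c37 (2.94 ± 0.23), the carboxylesterase Ces2c (3.44 ± 0.27) and Cyp2b10, the classic CAR target (3.94 ± 0.54, from 2.61 ± 2.36 to 47.6 TPM), were among them. PPARα targets rose in 6 of 43, 14 over the list alone (median 0.41, adjusted p = 1.57e-12, adjusted p = 0.170 with an estimated correlation). They included Cyp4a10 (5.39 ± 0.54), Cyp4a14 (5.35 ± 0.60), Ehhadh (1.95 ± 0.14) and the peroxisomal thiolase Acaa1b (2.98 ± 0.37). Lipogenesis genes rose in 3 of 22 and fell in 1, 8 and 1 over the list alone (median 0.93, adjusted p = 2.15e-07, adjusted p = 0.206 with an estimated correlation). Besides Thrsp and Scd1, Lpin1, a phosphatidate phosphatase, rose (1.84 ± 0.24) and Aacs, which activates acetoacetate for lipid synthesis, fell (-1.56 ± 0.22). LXR targets passed with Scd1, already counted among lipogenesis genes, as the called member (median 0.30, adjusted p = 6.78e-04, adjusted p = 0.233 with an estimated correlation). NRF2 targets passed with Gsta1, Gsta2 (1.68 ± 0.15) and Nqo1 (1.13 ± 0.18) called (median 0.35, adjusted p = 0.00406, adjusted p = 0.255 with an estimated correlation). Thyroid hormone responsive genes, with Thrsp called, rose as a list (median 0.64, adjusted p = 0.00238, adjusted p = 0.226 with an estimated correlation), and so did retinoid genes, with Cyp26a1 called (median 0.43, adjusted p = 0.0105, adjusted p = 0.170 with an estimated correlation).

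Among the remaining lists, cell cycle genes rose in knockout mice with 1 of 25 called, Rrm2 (1.5 ± 0.22), and 14 over the list alone (median 0.94, adjusted p = 1.12e-10, adjusted p = 0.170 with an estimated correlation). Bile acid genes (median 0.53, adjusted p = 4.85e-04), FXR-induced genes (median 0.45, adjusted p = 0.0417) and genes of glucose metabolism (median 0.38, adjusted p = 0.0362) were higher. So were amino acid catabolism (median 0.27, adjusted p = 0.00406) and pericentral genes (median 0.28, adjusted p = 0.0417), with Aldh3a2 (1.47 ± 0.19) the 1 called gene among these 5 lists. With an estimated correlation none of them passed, with adjusted p from 0.206 for bile acid genes to 0.373 for glucose metabolism. Acute phase genes, secreted by the liver in inflammation, fell in 2 of 25, 7 over the list alone (median -0.62, adjusted p = 2.45e-11, adjusted p = 0.226 with an estimated correlation). Saa3 went from 39.5 ± 4.58 to 10.2 TPM (-1.85 ± 0.19) and Itih3 from 628 ± 124 to 240.4 TPM (-1.37 ± 0.22). Icam1, an adhesion molecule induced in inflammation, fell too (-1.23 ± 0.18), as did Tspan4 (-1.49 ± 0.23), Rtp3 (-1.14 ± 0.17) and Wwc1 (-1.06 ± 0.17). Complement and coagulation (median -0.28, adjusted p = 4.01e-09), hepatocyte identity (median -0.24, adjusted p = 0.00238) and stress genes (median -0.17, adjusted p = 0.0119) also fell as lists. So did male-biased (median -0.42, adjusted p = 1.56e-04) and neutrophil genes (median -0.39, adjusted p = 0.0417), while Cyp4a12b, on the male-biased list, rose (3.18 ± 0.19). With an estimated correlation none of these 5 passed, with adjusted p from 0.170 for stress genes to 0.345 for neutrophil genes. Macrophage markers were higher in 12 of 12 genes, none called (median 1.39, adjusted p = 3.21e-05, adjusted p = 0.345 with an estimated correlation). So were 13 of 13 mitochondrially encoded genes (median 0.58, adjusted p = 2.25e-06, adjusted p = 0.206 with an estimated correlation), 1 of them over the list alone. With the GC and length trend removed the mitochondrial list kept its call (median 0.31). Other cell markers were higher without passing: erythroid genes in 4 of 5 (median 1.96, adjusted p = 0.101) and lymphocyte markers in 4 of 5 (median 0.89, adjusted p = 0.113). Endothelial (median 0.17, adjusted p = 0.858) and cholangiocyte markers (median 0.95, adjusted p = 0.215) did not pass either.

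The count for the knockout was 25 without knockout control 2, 249 without knockout control 5, 22 and 27 without floxed bexarotene 3 and 1, 35 without floxed control 4 and 34 without floxed controls 1 and 3. The calls of Cyp2b10, Acaa1b, Lpin1, Aacs, Nqo1, Rrm2, Aldh3a2, Itih3, Icam1, Tspan4, Rtp3 and Wwc1 were each lost in at least 1 of these fits or without knockout control 1 or floxed bexarotene 4, with adjusted p up to 0.0587 for Aldh3a2 and 0.132 for Nqo1. Of the lists, retinoid (0.102), NRF2 (0.0515) and amino acid genes (0.116) lost their calls without knockout control 2, stress genes (0.103) without knockout control 5, and FXR-induced (0.239), glucose (0.129), pericentral (0.145) and neutrophil genes (0.331) without either or without a treated knockout library.

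The direct test of the difference asked which genes responded to bexarotene by unequal amounts in the 2 genotypes. It called 22 genes, 11 with a larger and 11 with a smaller value in the knockout. With no filter 636 were larger and 53 smaller. Cyp2c29 rose more in the knockout by 3.61 ± 0.21 on the log2 scale (adjusted p = 0.00122): it was already at 2158 ± 63.9 TPM in floxed controls and 2999 ± 115 with the drug. Thrsp (2.65 ± 0.18, adjusted p = 0.00190) and Gsta1 (3.55 ± 0.35, adjusted p = 0.0118) differed in the same direction. Ehhadh (-2.25 ± 0.18, adjusted p = 0.00508), Ccnd1 (-3.10 ± 0.28, adjusted p = 0.00846) and Acsl1 (-1.68 ± 0.20, adjusted p = 0.0227) had a smaller value in the knockout. Ccnd1 stood at 0.703 ± 0.215 TPM there without the drug and 2.04 with it. Cyp4a14 (-0.92 ± 0.77, adjusted p = 0.768) and Cyp26a1 (-0.19 ± 0.68, adjusted p = 0.956) did not differ by this test; these 2 were chosen after their values were seen.

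PPARα targets had a smaller response in the knockout, with 2 of 43 called and 8 over the list alone (median -0.47, adjusted p = 5.66e-07, adjusted p = 0.416 with an estimated correlation). CAR and PXR targets had a larger one, with 5 of 36 called, and 13 larger and 4 smaller over the list alone (median 0.45, adjusted p = 3.17e-05, adjusted p = 0.0965 with an estimated correlation). This larger response started from a lower level. The mean log2(TPM + 1) of the list was 5.57 to 5.69 in knockout controls and 6.37 to 6.42 in floxed controls. With bexarotene it was 7.05 to 7.15 in both genotypes. Under bexarotene the list did not differ between genotypes by camera (median -0.015, adjusted p = 0.331), with 18 members higher and 18 lower. In the test of the difference, macrophage markers were higher in 12 of 12 genes (median 1.99, adjusted p = 5.66e-07, adjusted p = 0.533 with an estimated correlation). Mitochondrially encoded genes passed it too (median 0.66, adjusted p = 9.68e-05, adjusted p = 0.462 with an estimated correlation). The mitochondrial call was lost with the GC and length trend removed (median 0.31, adjusted p = 0.318). The count of 22 was 3 without floxed bexarotene 1, 6 without floxed bexarotene 3, 8 without knockout control 2, 11 without floxed control 4, 13 without floxed controls 1 and 3 and 209 without knockout control 5; Cyp2c29, Thrsp and Ehhadh were called in each fit. Gsta1 and Ccnd1 lost their calls without floxed bexarotene 1 (adjusted p = 0.0555 and 0.0536), and Acsl1 without that or 5 other samples (adjusted p up to 0.146).

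Across genes, the bexarotene effects in the 2 genotypes correlated weakly, with r = 0.123 and rho = 0.0397 over 11018 genes, which are not independent replicates. The jackknife SE of this r, from leaving out each sample except the treated knockout, was 0.129, about as large as r. With single libraries left out r ran from 0.0537 to 0.188. Of the 234 genes called in floxed mice, 187 (79.9%) had the same sign in the knockout, against 53.3% of all genes. The median absolute log2 fold change of these genes was 1.19 in floxed mice, and the median in the knockout, signed by the floxed direction, was 0.36; selection on the floxed values inflates the first of these. Of the genes called in both genotypes 20 were higher in both and 0 lower in both, where independent lists would give 0.848 and 0.0309. Cyp4a14, Cyp26a1, Ehhadh, Thrsp and Gsta2 are among them. Both tests used the same spread per gene, so genes of low spread can pass in both more easily. The values for independent lists may thus be too low as a yardstick.

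**Figure D3:**
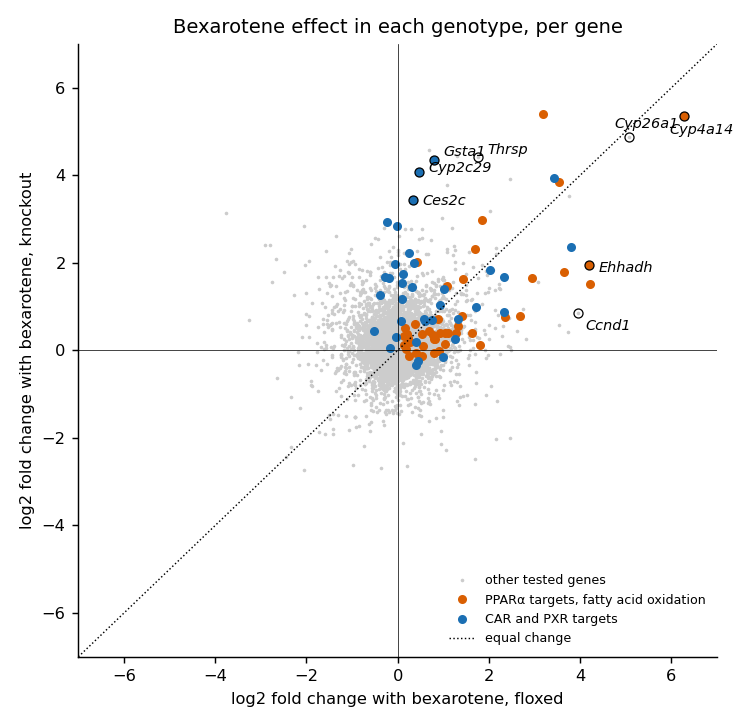
Each point is a tested gene; the x axis is its log2 fold change with bexarotene in floxed mice and the y axis that in knockout mice, with PPARα targets in orange, CAR and PXR targets in blue and the dotted line marking equal change. Ehhadh (4.20 and 1.95) and Ccnd1 (3.95 and 0.84) lie below the line, and Cyp2c29 (0.47 and 4.08), Gsta1 (0.80 and 4.35) and Ces2c (0.34 and 3.44) above it.

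Without the drug, CAR and PXR targets and PPARα targets were lower in the knockout, and acute phase and cholesterol synthesis genes were higher. None of the 17 list calls of this comparison held with an estimated correlation (adjusted p = 0.121, 0.267, 0.337 and 0.431 for these lists). Cyp2c29 fell from 2158 ± 63.9 TPM (n = 2) to 75.2 ± 10.3 TPM (n = 3; log2 fold change -4.83 ± 0.13, adjusted p = 1.16e-06). Thrsp fell from 437 ± 5.52 to 15.1 ± 1.35 TPM (-4.77 ± 0.11, adjusted p = 6.75e-07). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 34.5 ± 0.548 to 363 ± 62.5 TPM (3.35 ± 0.34, adjusted p = 0.00189). The asparagine synthetase Asns rose from 3.61 ± 0.343 to 40.6 ± 13.5 TPM (3.13 ± 0.35, adjusted p = 0.00304). The test called 414 genes, 202 higher and 212 lower. When the 20 most abundant and the mitochondrial genes were left out, 32.9% of the calls were higher in place of 48.8%, and the median of all genes moved to -0.113. Other settings turned the split the other way. The planned fit to 12 libraries called 739 higher and 563 lower, and array weights 718 and 516. Without knockout control 5 the calls were 432 higher and 331 lower.

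CAR and PXR targets fell in 12 of 36 members and rose in 1, 13 and 5 over the list alone (median -0.13, adjusted p = 5.83e-05, adjusted p = 0.121 with an estimated correlation). Cyp2c37 fell from 223 ± 69.6 to 3.74 ± 0.257 TPM (-5.53 ± 0.18), with Ces2c (-3.72 ± 0.22) and Cyp2c50 (-2.63 ± 0.13) also lower; the Cyp2c genes are near-identical copies, so reads may be split unevenly among them. PPARα targets fell in 9 of 43, 19 over the list alone (median -0.42, adjusted p = 6.53e-10, adjusted p = 0.267 with an estimated correlation). These included Acaa1b (-4.79 ± 0.29), Cyp4a10 (-4.16 ± 0.42), Aldh3a2 (-2.78 ± 0.15) and Vnn1 (-2.30 ± 0.18), a pantetheinase. Thyroid hormone responsive genes fell in 3 of 11, 4 over the list alone (median -0.39, adjusted p = 4.11e-04, adjusted p = 0.267 with an estimated correlation). They were Thrsp, Dio1, the deiodinase that activates thyroid hormone (-3.70 ± 0.52), and malic enzyme Me1 (-2.30 ± 0.33). Lipid droplet and PPARγ genes fell in 4 of 15, 6 over the list alone (median -0.35, adjusted p = 0.00298, adjusted p = 0.267 with an estimated correlation). Pparg (-1.33 ± 0.29) and Mogat1 were among them. Mogat1 was listed at 0.88, 0.65 and 1.31 TPM in the floxed controls and at 0 in all 3 knockout controls. Bile acid genes fell on balance, with 2 down and 1 up of 21, 6 and 1 over the list alone (median -0.26, adjusted p = 0.00207, adjusted p = 0.274 with an estimated correlation). The exporters Abcc3 (-3.13 ± 0.29) and Abcb4 (-0.82 ± 0.14) fell and Cyp7b1, of the alternative pathway, rose (1.15 ± 0.25). FXR-induced genes fell with 1 up and 1 down of 10, 1 and 5 over the list alone (median -0.44, adjusted p = 0.0239, adjusted p = 0.373 with an estimated correlation), and Lpl fell (-2.45 ± 0.19).

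Acute phase genes rose in 9 of 25, 10 over the list alone (median 0.74, adjusted p = 5.65e-09, adjusted p = 0.337 with an estimated correlation). Their mean log2(TPM + 1) was 9.16 in knockout control 5, 8.42 and 8.31 in knockout controls 1 and 2, and 7.54 to 7.93 in floxed controls. The list kept its call without knockout control 5 (median 0.52) and without floxed controls 1 and 3 (0.46). Among them were Lcn2, an iron-scavenging lipocalin (3.46 ± 0.42, 26.7 ± 10.04 to 329 ± 202 TPM), Orm2 (2.58 ± 0.19) and Saa3 (1.24 ± 0.15). Cholesterol synthesis and uptake genes rose in 5 of 26, 10 over the list alone (median 0.52, adjusted p = 9.53e-06, adjusted p = 0.431 with an estimated correlation). Msmo1, a sterol demethylation enzyme, rose (1.40 ± 0.26). Complement and coagulation genes rose in 2 of 30 (median 0.20, adjusted p = 8.57e-04, adjusted p = 0.520 with an estimated correlation). Clock genes rose as a list with 0 of 17 called (median 0.34, adjusted p = 0.0305, adjusted p = 0.267 with an estimated correlation). Hepatocyte identity genes rose in 2 of 23, 5 up and 1 down over the list alone (median 0.34, adjusted p = 0.00661, adjusted p = 0.373 with an estimated correlation). The 2 were Ttr (0.90 ± 0.15) and Apoa1 (0.92 ± 0.18), which encode major secreted proteins. Pericentral genes fell in 3 of 16, 6 over the list alone (median -0.19, adjusted p = 0.00207, adjusted p = 0.267 with an estimated correlation). They were Aldh3a2, the glutamine synthetase Glul (-1.96 ± 0.35) and the ammonium transporter Rhbg (-2.21 ± 0.30). Cell cycle genes fell as a list with 0 of 25 called (median -0.26, adjusted p = 0.00207, adjusted p = 0.431 with an estimated correlation).

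The major urinary protein genes Mup17 (-7.86 ± 0.55), Mup19 (-6.50 ± 0.55) and Mup15 (-4.81 ± 0.50) fell and Mup21 rose (2.57 ± 0.26); they are close copies of each other, and their values are uncertain for that reason. The male-biased list did not pass (median 0.35, adjusted p = 0.238; its mean was negative), nor did the female-biased one (median 0.23, adjusted p = 0.827; negative mean). In the latter Cyp2c69 (-3.35 ± 0.36) and Cyp2c40 (-2.88 ± 0.36) fell and Cyp17a1 rose (3.28 ± 0.68). Nat8f7 (3.86 ± 0.20), the pseudogene Cyp2d41-ps (3.52 ± 0.26) and the trefoil peptide Tff3 (3.36 ± 0.34) rose, as did the protease inhibitor Serpine2 (3.22 ± 0.61), and Cyp4a12b, a male-biased cytochrome, fell (-5.27 ± 0.15). Mitochondrially encoded genes were lower in 13 of 13, 1 called and 10 over the list alone (median -0.62, adjusted p = 1.49e-07, adjusted p = 0.267 with an estimated correlation). The called gene, mt-Nd1, went from 8887 ± 385 to 4767 ± 345 TPM (-0.90 ± 0.12). With the GC and length trend removed the mitochondrial list kept its call (median -0.38). Mitochondrial genes took 7.62% to 9.61% of the knockout control libraries and 12% to 15.8% of all others. Macrophage markers were lower in 12 of 12 genes, none called (median -0.97, adjusted p = 7.63e-04, adjusted p = 0.520 with an estimated correlation). Of the lymphocyte markers 5 of 5 were lower (median -0.70, adjusted p = 0.0211, adjusted p = 0.503 with an estimated correlation). Without floxed control 4 neither list kept its call, and the macrophage median was -0.27. Knockout control 5, the knockout control with the highest macrophage level (1.91), stayed in that fit.

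The count of 414 was 103 without floxed control 4, 105 without floxed controls 1 and 3, 219 without knockout control 2, 253 and 272 without floxed bexarotene 1 and 3 and 763 without knockout control 5. The calls of Dio1, Me1, Pparg, Mogat1, Abcb4, Cyp7b1, Lcn2, Saa3, Msmo1, Ttr, Apoa1, Glul, Rhbg, Cyp2c40, Cyp17a1, Serpine2 and mt-Nd1 were lost without floxed controls 1 and 3 or, for most of them, other single libraries, with the highest adjusted p between 0.0518 for Lcn2 and 0.252 for Cyp7b1. Complement and hepatocyte identity genes (both 0.0515) lost their list calls without knockout control 1, pericentral genes (0.0532) without floxed controls 1 and 3, and clock (0.144), cell cycle (0.134) and FXR-induced genes (0.137) without floxed control 4 or other samples.

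**Figure D4:**
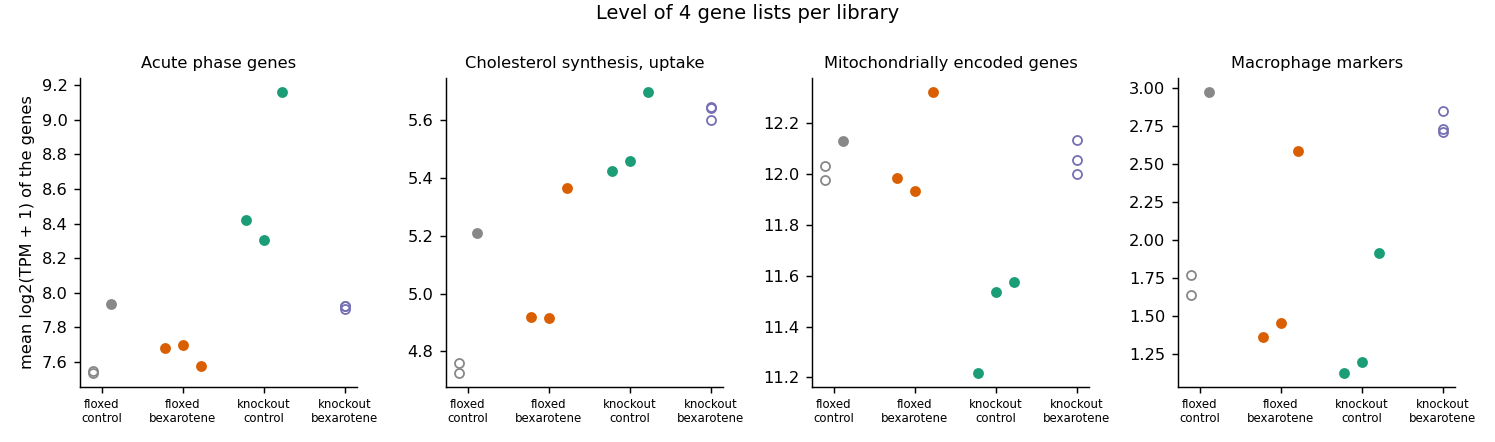
Mean log2(TPM + 1) of 4 gene lists (y axes) per library in the 4 groups; open circles are libraries averaged into 1 sample and filled circles are single samples, and the y axes do not start at 0. The list medians for the knockout without the drug were 0.74 for acute phase genes, 0.52 for cholesterol genes, -0.62 for mitochondrially encoded genes and -0.97 for macrophage markers.

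Under bexarotene, PPARα targets were lower in the knockout than in floxed mice in 16 of 43 members, 28 over the list alone (median -1.15, adjusted p = 9.21e-31, adjusted p = 0.0654 with an estimated correlation). Ehhadh stood at 1754 ± 94.3 TPM in treated floxed samples (n = 3) and 365 in the treated knockout (n = 1; log2 fold change -2.26 ± 0.14, adjusted p = 5.30e-04), and Vnn1 (-2.45 ± 0.23) and Acot2 (-2.48 ± 0.24) were lower too. Apoa4 was higher, at 1470.0 against 90.7 ± 47.7 TPM (4.12 ± 0.43, adjusted p = 0.00298), and so were Lpin1 (3.09 ± 0.24), Gsta1 (2.99 ± 0.28) and Asns (3.58 ± 0.45). Cyp2c29 was lower by a smaller margin, -1.22 ± 0.17. Ccnd1 (-3.84 ± 0.22), Cidec (-2.69 ± 0.25), Dio1 (-4.48 ± 0.66), Thrsp (-2.12 ± 0.14) and Mup17 (-6.74 ± 0.70) were lower. The test called 213 genes, 75 higher and 138 lower. This split was not stable: with no filter 853 were higher and 188 lower, and with all 12 libraries as separate samples 795 were higher and 794 lower.

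Of the lists, cholesterol genes were higher (median 0.62, adjusted p = 7.63e-04, adjusted p = 0.788 with an estimated correlation), with 0 of 26 called and 5 up and 1 down over the list alone. NRF2 targets were higher too (median 0.27, adjusted p = 0.0300, adjusted p = 0.715 with an estimated correlation), with Gsta1 called and 3 over the list alone. FXR-induced genes (median -0.45, adjusted p = 0.00500, adjusted p = 0.431 with an estimated correlation) and lipid droplet genes (median -0.48, adjusted p = 0.00240, adjusted p = 0.361 with an estimated correlation) were lower. The RXR isotypes (median -0.25, adjusted p = 0.0414, adjusted p = 0.423 with an estimated correlation) and cholangiocyte markers (median -0.48, adjusted p = 0.0246, adjusted p = 0.391 with an estimated correlation) were lower too. These 4 lists had Slc51b (-2.31 ± 0.20), Cidec, Rxra and Krt23 (-1.65 ± 0.29) as called members. Rxra is the deleted gene, so the call of its list says little about the other RXR genes. Macrophage (median 1.01, adjusted p = 0.00488, adjusted p = 0.788 with an estimated correlation) and endothelial markers (median 0.24, adjusted p = 0.0414, adjusted p = 0.788 with an estimated correlation) were higher in 12 of 12 genes each. The count of 213 was 91 without floxed bexarotene 1, 105 without floxed bexarotene 3 and 432 without knockout control 5. Krt23 lost its call without floxed control 4, floxed controls 1 and 3 or floxed bexarotene 1 (adjusted p up to 0.0865). FXR-induced (0.281), NRF2 (0.0604), endothelial (0.166) and RXR isotype lists (0.082) lost their calls without floxed bexarotene 3 or 4 or, for the last 3, other single libraries.

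The knockout effect in controls and the bexarotene effect in floxed mice both use the floxed controls. Their log2 fold changes correlated with r = 0.266 (jackknife SE 0.176) and rho = 0.341 across genes. In 100 simulated sets of unchanged groups against the same controls the mean r was 0.600. Each sample was given the same spread per gene there, so this r follows from the sample numbers alone. The covariance was 0.0635 against a simulated 0.0465, a difference of 0.0170. Beyond counting noise, knockout controls differed from each other by 0.250 to 0.503, and floxed control 4 from 1 and 3 by 0.165 and 0.151. The simulated spread may thus be too large for the shared controls, and no conclusion is drawn from the difference. Genes such as Abcg8, higher in both, numbered 29, and 5 were lower in both, where independent lists would give 3.72 and 0.596. Those higher with bexarotene and lower in the knockout, such as Thrsp, numbered 25, and 2 went the other way, against 3.91 and 0.568. The floxed controls were not split, since each part would hold only 1 sample, so part of the excess in the same direction may come from the shared controls. Both tests also used the same spread per gene, so part of the excess in either direction may come from genes of low spread. Without floxed controls 1 and 3 the correlation was 0.437.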

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

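The tests on the treated knockout group itself, on macrophage markers and on clock genes were chosen only after those results were seen, while the test for repeated libraries and the counts over other splits were fixed before their values were seen but after close libraries had been averaged.

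The bexarotene effect differed between genotypes, by a direct test, for 22 genes. The log2 difference, knockout minus floxed, was 3.61 for Cyp2c29, 3.55 for Gsta1, 3.16 for Cyp2c37, 3.11 for Ces2c, 2.65 for Thrsp, 2.63 for Lpin1, 2.29 for Mgst2 and 2.04 for Cyp2c50. It was -1.68 for Acsl1, -1.76 for Aass, -2.25 for Ehhadh, -2.32 for Alpl, -2.37 for Pla2g6, -2.39 for Aacs, -2.48 for Cidec, -2.55 for Slc16a5, -2.94 for Maats1os and -3.10 for Ccnd1. Only Cyp2c29, Thrsp and Ehhadh kept the call in every fit without a library; the highest adjusted p of the others ran from 0.0536 for Ccnd1 to 0.194 for Alpl. Mgst2 was listed at 0 in all 6 floxed libraries and at 0.28, 0.75 and 0.49 TPM in knockout controls and 4.9, 6.46 and 7.63 in treated knockout libraries. Maats1os was listed at 0 in all control libraries of both genotypes and at 13.5, 8.56 and 10.1 TPM in treated floxed mice and 0, 0.8 and 0.71 in the treated knockout.

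Among lists the median differences that passed the same test were -0.47 for PPARα targets, 0.45 for CAR and PXR targets, 0.59 for bile acid genes, 0.66 for thyroid hormone responsive genes, -0.33 for acute phase genes, -0.15 for complement and coagulation genes, -0.38 for clock genes, 0.58 for pericentral genes, 1.99 for macrophage markers, 1.33 for lymphocyte markers and 0.66 for mitochondrially encoded genes. None passed with an estimated correlation, where the smallest adjusted p was 0.0965 for CAR and PXR targets. Without knockout control 5 the acute phase median was 0.25 and its call was lost (adjusted p = 0.361). Bile acid (0.052), clock (0.109), complement (0.0712), lymphocyte (0.0512) and thyroid genes (0.0931) also lost theirs without 1 library or sample.

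Some libraries of one group were close to identical. If one RNA sample or library were present more than once, genes that vary most elsewhere should differ within these pairs by less than 1.5 times as much as other genes of the same expression. For 500 such genes, taken from other groups, the ratio was 1.02, 1.20, 1.35 and 1.417 in the close pairs. It was at least 1.64 in the 6 other pairs tested, which fits this explanation by that limit. The close pairs were picked for a small spread beyond counting noise, which by itself draws the ratio towards 1. The test therefore repeats part of that choice and cannot alone show that 1 sample was present more than once. That the treated knockout animals respond alike cannot be the whole cause, since 1 close pair lies among the floxed controls. Pooled RNA could give the same picture and was not tested.

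Macrophage markers were higher in the treated knockout than the other groups predict. Among markers of other cells the median differences between genotypes were 2.12 for erythroid, 1.33 for lymphocyte, 0.84 for neutrophil, 0.38 for endothelial and -0.38 for cholangiocyte genes, against 1.99. A lower share of hepatocytes, with RNA of all other cell types raised alike, cannot be told apart from a change in macrophages alone, since no gap between macrophage markers and these 5 lists passed a test against the spread between samples (smallest adjusted p = 0.0568, for neutrophil markers). A change of macrophages by bexarotene in the knockout cannot be told apart from spread between samples, since their level rose by 1.354 over knockout controls while samples of 1 group differed by up to 1.26. The level was 1.71 and 2.97 in the floxed controls and 2.77 in the treated knockout, which is in effect 1 sample. It was 1.36, 1.45 and 2.59 in treated floxed samples and 1.13, 1.20 and 1.91 in knockout controls. Floxed control 4, floxed bexarotene 4 and knockout control 5 thus stood above the rest of their groups. Whatever set these samples apart cannot be told apart from an effect of bexarotene in the treated knockout.

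Clock genes differed between groups and within them. The gap between 8 evening and 3 morning genes rose by 3.23 with bexarotene in floxed samples, where it ranged over 0.669 within the controls and 0.771 within the treated group. Within the knockout controls it ranged over 3.584, from -1.97 in control 5 to 1.29 and 1.61 in the others; samples taken at different times of the daily cycle fit this range, which rests on control 5, but sampling times are not given in the sources used here. A shift of clock genes by bexarotene in both genotypes cannot be told, since the change in the knockout was 0.5076, smaller than that range. A shift by bexarotene in floxed mice alone was not tested and stays open. The gap was -0.869 and -1.54 in floxed controls and 1.76 to 2.53 in treated floxed samples. For other genes that follow the daily cycle, sampling time thus cannot be told apart from bexarotene in floxed mice. Knockout controls 1 and 2, but not 5, also lay above the floxed controls. The knockout effect without the drug shares this limit in part.

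The number of called genes was compared with other splits of the same samples. The real split called the most genes both for bexarotene in floxed mice (1 of 10 splits, real 234, highest other 6) and for the knockout without the drug (1 of 10, real 414, highest other 166). These splits are too few for a share under 0.05.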

How the results depend on the processing

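The averaging of close libraries and the fits that average a further pair, leave out both averaged floxed controls, remove the GC and length trend or add a block were chosen only after the data were seen, while the fit to 12 separate libraries was the planned one. No called gene or list test reversed its direction. List medians changed sign for acute phase genes in the difference between genotypes (-0.33, 0.25 without knockout control 5) and macrophage markers in floxed mice (-0.55, 0.04 without floxed control 4). That of cholangiocyte markers in the knockout under bexarotene went from -0.48 to 0.01 with no filter. There the calls of this comparison turned from mostly lower to mostly higher (853 higher, 188 lower). Counts below are in the order bexarotene in floxed mice, bexarotene in the knockout, knockout without and with bexarotene, and difference between genotypes, against 234, 57, 414, 213 and 22.

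The counts were 1062, 1105, 1302, 1589 and 651 with all 12 libraries as separate samples, and 88, 25, 272, 116 and 7 when the next closest pair was averaged too; more or fewer samples by construction. They were 1279, 218, 1234, 667 and 210 with array weights and 140, 875, 231, 1041 and 689 with no filter. With only the compared groups in the fit they were 614, 6 and 158 for the first 3. The knockout without bexarotene gave 261 with an absolute log2 change of at least 1. Removal of the GC and length trend gave 605 and 320 for the knockout without and with bexarotene and 36 for the difference. The difference had 14 calls without the 20 most abundant and the mitochondrial genes. Log2 ratios of knockout control 1 to controls 2 and 5 correlated with GC content (rho = 0.645 and 0.531), as did those of floxed bexarotene 1 to 3 (-0.512). In the other pairs of a group rho lay between -0.332 and 0.308. The removal cut the spread of knockout control 1 against 2 from 0.348 to 0.206 and against 5 from 0.503 to 0.351. Leaving out single libraries gave 47 to 554, 22 to 249, 103 to 763, 91 to 432 and 3 to 209. Except where stated, the cause was not tested.

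With an estimated correlation 3 of 76 list calls held. With single libraries left out 68 to 76 list calls were made, and 83 without both averaged floxed controls. Of 203 calls of named genes, 203 held with 12 libraries, 196 and 188 with pseudocounts of 0.5 and 0.1, 184 with the median ratio, 190 with quantile normalization, 194 with the GC and length trend removed, 187 with the 5 TPM filter (5 lost, the others no longer tested), 150 with no filter and 128 with the next pair averaged. Totals per fit hide that calls were lost in one fit and gained in another. Fewer calls held in every fit that left out libraries. In the order above these were 12 of 18, 13 of 21, 8 of 17, 5 of 9 and 5 of 11 list calls. For named genes they were 21 of 52, 13 of 26, 26 of 67, 24 of 40 and 3 of 18. With the GC and length trend removed, the mitochondrially encoded list lost its call in the difference between genotypes (median 0.31, adjusted p = 0.318). The correlation of the bexarotene effects was 0.606 over genes called in floxed mice, which selection inflates, and 0.0537 to 0.188 over single libraries left out; that of the knockout and bexarotene effects was 0.198 to 0.297, and 0.437 without both averaged floxed controls. The median of all genes for bexarotene in the knockout was 0.127 and 0.112 with pseudocounts of 0.1 and 0.5, 0.102 without the most abundant genes and 0.147 without knockout control 2, against 0.0976. It was lower with array weights (0.0345), the GC and length trend removed (0.0168), the median ratio (0.0146), no filter (0.00954) and quantile normalization (-0.0306).

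The columns number the libraries differently from the titles, and no source says that a number marks a shared day or litter. Floxed control and bexarotene libraries share the numbers 1, 3 and 4. The deviations from their group means correlated by 0.0361, 0.00529 and 0.143 for these numbers. Floxed control 3 correlated best with bexarotene 1 (0.161), and floxed control 4 by -0.160 and -0.00359 with bexarotene 1 and 3. Control 4 and bexarotene 4 also had the highest macrophage marker levels of their groups (2.97 and 2.59). Floxed controls 1 and 3 were close to identical and deviations cancel within a group, so these values cannot settle whether the numbers mark pairs. The numbers were not taken as pairs because no source says so. With the number as a replicate block in floxed samples, 69 genes were called for bexarotene in floxed mice, and the macrophage list kept its call (median -0.34, adjusted p = 0.00109). With the block over 12 separate libraries the counts were 1771, 1744, 1438, 1819 and 1799. In that fit some results not called above were called in the other direction. They were Car3 for bexarotene in the knockout (-0.42), and endothelial (0.38) and erythroid lists (0.57) for the knockout without bexarotene, where the groups share only 1 number. The acute phase median of the difference was 0.11 there.

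The depth is unknown, so how far it limits low genes cannot be stated.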

Other observations

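The genes in this part were chosen only after their values were seen, and no tests were run on them as a set. Values are TPM per library in the order of the column numbers.

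Several liver genes varied widely within groups. Cyp2a4, a female-biased steroid hydroxylase, stood at 0.87, 1.06 and 88.4 in floxed controls, 1.56, 1.83 and 204 in treated floxed mice, 0.04, 0 and 0 in knockout controls and 0.37, 0.17 and 0.19 in the treated knockout. Cdkn1a, an inhibitor of the cell cycle, stood at 74.0, 73.5 and 72.6 in floxed controls, 27.1, 26.6 and 6.38 in treated floxed mice, 3.08, 1.99 and 71.9 in knockout controls and 70.4, 64.0 and 69.7 in the treated knockout. Values of the hepcidin gene Hamp, which limits iron uptake, were 3333, 3269 and 367 in floxed controls, 6069, 5819.7 and 3373 in treated floxed mice, 4469, 3737 and 5094 in knockout controls and 1086, 1057 and 1091 in the treated knockout. Those of Angptl4, an inhibitor of lipoprotein lipase, were 63.3, 68.5 and 72.4 in floxed controls, 86.4, 86.9 and 106 in treated floxed mice, 12.9, 10.5 and 77.4 in knockout controls and 94.1, 90.0 and 95.9 in the treated knockout.

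The protease inhibitor gene Serpina1e, 1 of several close copies, was at 10033, 10092 and 14741 in floxed controls, 3906, 4361 and 1460.4 in treated floxed mice, 30015, 23272 and 20356 in knockout controls and 3717, 3621 and 3639.9 in the treated knockout. Pdk4, which spares glucose in fasting, was at 1.46, 1.18 and 1.84 in floxed controls, 3.69, 2.96 and 17.3 in treated floxed mice, 3.07, 4.72 and 10.9 in knockout controls and 19.9, 18.6 and 19.1 in the treated knockout.

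The immediate early genes Egr1 and Fos and the macrophage marker Clec4f were highest in the same libraries of the floxed groups and the knockout controls. Egr1 was at 1.61, 2.29 and 21.1 in floxed controls, 0.73, 0.35 and 15.7 in treated floxed mice, 1.7, 2.78 and 11.8 in knockout controls and 17.2, 17.2 and 16.8 in the treated knockout. Fos was at 3.99, 2.98 and 25.2 in floxed controls, 1.25, 0.9 and 12.8 in treated floxed mice, 0.64, 1.48 and 5.23 in knockout controls and 7.15, 6.76 and 7.51 in the treated knockout, and Clec4f at 4.09, 4.91 and 16.4 in floxed controls, 4.25, 4.61 and 14.4 in treated floxed mice, 1.76, 3.68 and 6.11 in knockout controls and 17.5, 14.4 and 15.5 in the treated knockout. In the knockout controls the clock gene Dbp was at 44.5, 33.4 and 1.04 and Arntl, which peaks at the opposite time of day, at 1.64, 2.84 and 13.4.

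The predicted gene Gm8186 differed by column position in the same order in every group, also among libraries that were otherwise close to identical. It was at 55.0, 27.5 and 0 in floxed controls, 49.7, 29.0 and 17.1 in treated floxed mice, 58.1, 28.9 and 0 in knockout controls and 52.9, 27.9 and 19.2 in the treated knockout.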
